A study of Rattus norvegicus with 6 samples.

How the data were processed

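Small RNA was sequenced from the orbitofrontal cortex of adult male rats of the outbred Sprague Dawley stock, with 3 libraries from sham-operated animals and 3 from animals given repeated controlled cortical impact. The labels describe 3 biological replicates per group, name no batch and give no pairing, so replicate numbers only name libraries. Per the labels' protocols, libraries were built from total RNA with a ligation-based small RNA kit and size-selected on a gel. Per the submitters' processing notes, Bowtie and the rat build rn6 were used, with no version given. The read counter, the miRNA annotation release and any read filter are not given in the sources used here.

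The authors deposited 1 table of 842 rows, of which 676 carried miRBase names and 166 were predicted miRNAs without such a name. Per the file headers, it held a raw read count and a TPM value per library. The deposited TPM values equalled the deposited counts divided by the column total and scaled to a column sum of 1000000, with no length term, to within 4.66e-10. All tests below therefore used the deposited counts, and TPM entered only 1 alternative. Totals per library were 12538288, 19446526 and 23680840 counted reads in sham and 22311086, 17244114 and 21884270 in injured animals. At these depths, 3 counts, the upper limit that a count of 0 allows, corresponded to 0.127 to 0.239 CPM, the count scaled to a library total of 1000000. Floors and intervals on single libraries cover counting error only, since the reads carried no molecular identifiers. No pair of libraries agreed within sampling noise, with a chi-square per degree of freedom of at least 257, so none was counted as a duplicate.

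The following choices were made before the data were examined: the tests, the miRNA lists, the rule for naming miRNAs and most alternatives. Changed miRNAs were sought with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 with its defaults, TMM scaling, filterByExpr (minimum count 10, minimum total 15) and Benjamini-Hochberg adjustment over all miRNAs tested, with calls at an adjusted p of 0.05. The filter kept 534 miRNAs, 509 of them with miRBase names, holding 99.996% of reads. CPM values are TMM-scaled, and log2 fold changes are injured over sham. For edgeR the standard error was derived as the absolute log2 fold change divided by the square root of the F statistic. The 95% interval was built from this standard error with a t distribution. Arm usage was tested with limma 3.58.1 on the log2 ratio of 5p to 3p counts, with a pseudocount of 0.5, for hairpins with a mean count of at least 10 in each arm.

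Lists of miRNAs written from general knowledge covered neuron-enriched, activity-regulated, astrocyte-enriched, oligodendrocyte-enriched, microglial and immune, vessel and mural, erythrocyte, choroid plexus with ependyma and epithelium, caudal Hox-cluster and striated muscle miRNAs. Others held the sensory miR-183 cluster, miRNAs studied after brain injury, the imprinted Dlk1-Dio3 cluster, the miR-17/92 cluster with its paralogs, the miR-344 family and the let-7 family. Each of the 15 lists with at least 3 tested members was tested with camera from limma on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. The share of reads taken by each of the 16 lists was compared with an exact two-sided permutation test, which cannot go below p = 0.10 with 3 against 3.

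The rule for named miRNAs took up to 12 called in each direction. Where fewer than 10 were called, it took those with the smallest unadjusted p until 10 were named. It added the 5 most abundant, the 2 members of each tested list with the smallest p, 10 fixed names, and the 2 hairpins with the smallest p if no arm change was called. It gave 42 miRNAs, and others are named only as members of a list or as chosen after their values were seen.

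The procedures were tested on simulated counts drawn from the means and depths of these libraries. For injured against sham, with 525 simulated miRNAs tested, edgeR called 3 of 66 miRNAs changed 1.5-fold, 17 of 67 changed 2-fold and 58 of 64 changed 4-fold, and 1 of 328 unchanged ones. All these changes were placed in the same simulated set, which makes the adjustment more lenient than where few miRNAs differ. Over 20 simulated sets of 534 miRNAs with no change, a median of 23 miRNAs had an unadjusted p under 0.05, with a range of 15 to 31. In 20 sets, the erythrocyte list shifted 1.5-fold was called in 13 and unshifted in 0. Simulated miRNAs were drawn independently of one another, whereas the estimated correlation within a real list reached 0.93 for the miR-183 cluster. The 0 therefore does not measure how often camera calls an unchanged list in these data. Of 30 hairpins given a 4-fold arm change among 150, limma called 29, with 2 others.

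Alternatives covered the scaling (RLE, library totals, upper quartile), the filter, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1), robust fitting, predicted or most abundant miRNAs left out, families summed, other thresholds, other list tests and prior counts, other arm minimums and pseudocounts, other denominators for shares, and each library left out in turn. The legacy form of the edgeR fit, planned as an alternative, is the default of this version, so the other form was run in its place. Also added after seeing the data were fits with 1 row of each near-duplicate pair, without the 2 libraries highest in the miR-200 family, and with the level of that family as a covariate. Where a result had missed its threshold, an alternative counted as opposite in direction only if the difference exceeded its standard error, or for a list if camera gave a p under 0.32.

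Rows were called near-duplicates when their counts differed by at most 5% in every library at a mean of at least 50 reads. Gene neighbourhoods came from RefSeq on assembly GRCr8, which matched 671 of the 676 miRBase names. Since that assembly differs from rn6, it served only for names and for which loci overlap, and no coordinates are given.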

Results

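Small RNA profiles were obtained from the orbitofrontal cortex, a frontal region involved in decision making, of 6 adult male Sprague Dawley rats. Animals had 3 surgeries, on days 1, 4 and 7, and tissue was taken on day 42. In 3 animals each surgery delivered a controlled cortical impact, a blow from a piston, at 5 m/s to a depth of 2 mm. In the other 3 each surgery was a sham operation. The comparison asked which miRNAs differed in this region weeks after repeated mild traumatic brain injury. Libraries held 12538288 to 23680840 counted reads, and between 697 and 756 of the 842 listed miRNAs had at least 1 read. These totals, and the CPM values, floors and shares based on them, include the counts of both names in 30 pairs with nearly equal counts. Without the second names, which held 22.2% to 24.9% of reads, totals were 9447914 to 17788976. The 5 miRNAs highest in each library, which include 1 such pair, took 54.2% to 58.6% of its reads, and predicted miRNAs took 0.0109% to 0.0217%. Spearman correlations across miRNAs had a median of 0.979 over the 6 pairs of libraries within a group and 0.978 over the 9 pairs between groups.

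None of the 5 most abundant miRNAs of the orbitofrontal cortex passed the test of injured against sham animals. miR-9a-5p, a miRNA of neural progenitors and neurons, had 203883 ± 21612 CPM in sham and 202669 ± 16726 CPM in injured animals (SD, n = 3 each). The log2 fold change was -0.01, with a 95% interval from -0.29 to 0.27. miR-9b-3p, whose counts lay within 0.241% of those of miR-9a-5p in every library and which cannot be taken as a separate measurement, followed at 203441 CPM in sham. miR-128-3p, a neuronal miRNA, had 81357 ± 26807 CPM in sham and 99859 ± 13527 CPM in injured animals, and its log2 fold change of 0.30 had an interval from -0.26 to 0.85. miR-26a-5p and miR-143-3p had log2 fold changes of 0.24 ± 0.15 and 0.28 ± 0.25 (SE).

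The miRNAs with the smallest p-values were all lower in the injured group, and none of them passed the test. miR-214-3p, which is processed from the same transcript as miR-199a and is typical of mesenchymal cells, had 2.39 ± 0.90 CPM in sham and 0.629 ± 0.172 CPM in injured animals (SD, n = 3 each). Its log2 fold change was -1.94 ± 0.39 (SE), it was lower in every injured than in every sham library, and its adjusted p was 0.813. miR-451-5p, an abundant miRNA of red blood cells, had 56.6 ± 19.5 CPM in sham and 25.5 ± 8.2 CPM in injured animals, with a log2 fold change of -1.15 ± 0.32 and an adjusted p of 0.878. miR-6329 had 33.1 ± 3.8 CPM in sham and 22.0 ± 1.0 CPM in injured animals, a log2 fold change of -0.59 ± 0.17. Log2 fold changes of the other 7 were -0.91 for miR-337-3p, -0.49 for miR-190b-5p, -1.11 for miR-1912-3p, -0.66 for miR-195-5p, -0.60 for miR-15b-5p, -0.69 for miR-350 and -1.05 for miR-3542. Of these 10, only miR-3542 had overlapping groups. Some rested on few reads. In replicates 1, 2 and 3, miR-214-3p had 29, 28 and 90 reads in sham and 15, 12 and 10 in injured animals. miR-1912-3p had 9, 15 and 21 reads in sham and 11, 3 and 8 in injured animals, and miR-3542 had 15, 11 and 31 against 9, 5 and 15.

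**Figure D1:**
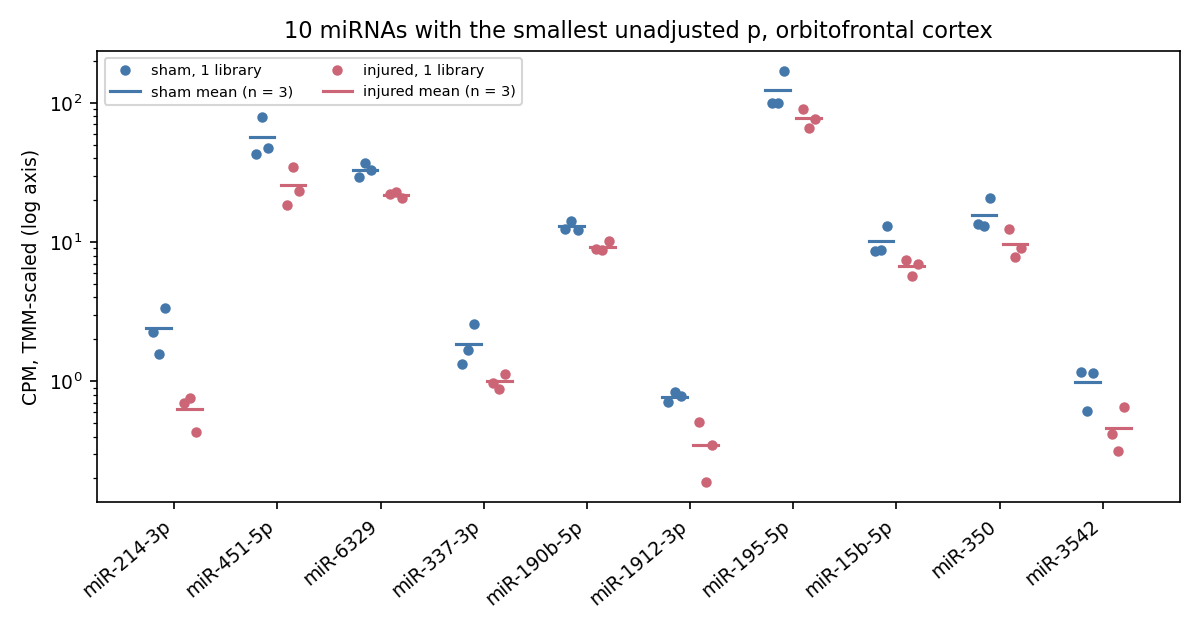
Level of the 10 miRNAs with the smallest unadjusted p in each library, in TMM-scaled CPM on a log axis, with points for single libraries and short lines for the means of 3 sham (blue) and 3 injured (red) animals. miR-214-3p averaged 2.39 CPM in sham and 0.629 CPM in injured animals, and none of the 10 passed the test after adjustment.

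With edgeR's quasi-likelihood test, 0 of 534 miRNAs passed an adjusted p of 0.05, with 0 higher and 0 lower, and the smallest adjusted p was 0.813. At an unadjusted p under 0.05 there were 12 miRNAs, 11 lower and 1 higher in injured animals, where chance alone gives 26.7. The 20 simulated sets with no change gave 15 to 31, all above 12. The real data thus gave fewer small p-values than the simulated sets, and the low count does not by itself show absence of change. DESeq2, limma-voom and limma on log2(TPM + 1) also called 0. The smallest adjusted p-values of DESeq2 were 0.052 for miR-214-3p and 0.0593 for miR-451-5p. The groups did not overlap for 42 miRNAs, 7.87% of those tested against the 10% that chance gives for 3 against 3, and 26 of them were lower in injured animals. The 95% interval of a typical miRNA reached 0.56 log2 units to either side, as the median over miRNAs. The biological coefficient of variation was 36.4% from the dispersion common to all tested miRNAs, which need not describe a typical miRNA. The 1 miRNA higher at an unadjusted p under 0.05, miR-292-5p, named here after its values were seen, had a log2 fold change of 4.80, and 579 of its reads came from injured replicate 1 against at most 28 in any other library. Leaving out the 2 libraries highest in the miR-200 family gave 1 call, miR-293-5p, with a log2 fold change of 4.53 and an adjusted p of 0.0318. Those 2 libraries ran against that difference, since miR-293-5p had 21, 3 and 3 reads in sham and 55, 1 and 88 in injured replicates 1, 2 and 3. With all libraries edgeR gave it a log2 fold change of 1.92 ± 1.27 (SE) and DESeq2 1.79 ± 1.60, at adjusted p-values of 0.878 and 0.961.

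The erythrocyte list fell in injured animals under camera with its preset correlation. Of its 6 tested members, 5 had negative and 1 had a positive log2 fold change, with a median of -0.63, at an adjusted p of 0.0424 (camera, 15 lists). With an estimated correlation the call was lost, at a camera adjusted p of 0.558 (unadjusted 0.0372), and fry gave an adjusted p of 0.181. The correlation estimated for this list was -0.058, below the preset 0.01. Stronger correlation among its members therefore does not explain the loss. Beside miR-451-5p, the members from its own transcript, miR-144-5p and miR-144-3p, had log2 fold changes of -0.82 and -0.65. miR-15b-5p and miR-16-5p, which are also expressed outside the blood, had -0.60 and -0.47, and miR-363-3p had 0.50 ± 0.52 (SE). None of the 6 was called over all miRNAs, and 0 were called when adjusted over the list alone, with a smallest adjusted p of 0.0501 from edgeR. The list took 0.0598% ± 0.0220 of reads in sham and 0.0392% ± 0.0092 in injured animals (SD, n = 3 each; exact permutation p = 0.3). In fits with 1 library fewer, the call was lost without sham replicate 2 (median -0.57, adjusted p = 0.151) and without injured replicate 3 (median -0.51, adjusted p = 0.124).

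Immune miRNAs and miRNAs studied after brain injury had negative medians with TMM scaling, and neither list passed the test. Of 34 tested miRNAs studied after brain injury, 25 had negative and 9 positive log2 fold changes, with a median of -0.19 (camera adjusted p = 0.0512), but with upper-quartile factors 18 were negative and 16 positive, with a median of -0.06. This list shared 6 members with the microglial and immune list, including miR-223-3p, miR-155-5p, miR-146a-5p and miR-21-5p, so these lists are not separate observations. Other overlaps included 7 members with the neuron-enriched and 5 with the activity-regulated list. The brain injury list also shared miR-451-5p, miR-144-3p and miR-16-5p with the erythrocyte list and miR-214-3p and miR-199a-3p with the vessel list. In the microglial and immune list, 10 of 13 members were negative, with a median of -0.25 (camera adjusted p = 0.135), and with upper-quartile factors 8 were negative, with a median of -0.10. miR-223-3p, a miRNA of myeloid cells, had 2.15 ± 0.88 CPM in sham and 1.10 ± 0.42 CPM in injured animals (SD, n = 3 each), a log2 fold change of -0.98 ± 0.43 (SE). miR-342-3p had -0.66 ± 0.33, the inflammation-associated miR-155-5p -0.48 ± 0.30 and miR-146a-5p -0.40 ± 0.25, while miR-21-5p, which responds to injury in many tissues, had -0.09 ± 0.18 at 7024 CPM in sham and 6620 CPM in injured animals. In both lists 0 members were called over all miRNAs and 0 when adjusted over the list alone. With an estimated correlation the camera adjusted p was 0.59 for both. The brain injury list passed at adjusted p-values of 0.0313 without sham replicate 2, 0.0314 without sham replicate 3 and 0.035 without injured replicate 1. It also passed with library totals in place of TMM, at 0.0464, and with 1 row per near-duplicate pair, at 0.04995.

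Neuron, activity, astrocyte and oligodendrocyte lists had medians between -0.17 and 0.08 on the log2 scale, and none passed the test. Of 24 neuron-enriched miRNAs, 13 had positive and 11 negative log2 fold changes. The median was 0.08, camera's direction was up and the mean was -0.003 (camera adjusted p = 0.696). miR-124-3p, the most specific of the neuronal miRNAs, had 4782 ± 1086 CPM in sham and 4610 ± 771 CPM in injured animals (SD, n = 3 each), a log2 fold change of -0.05 ± 0.20 (SE). miR-129-1-3p and miR-129-2-3p had identical counts in every library and a log2 fold change of -0.60 ± 0.27. Of 13 activity-regulated miRNAs, 7 were negative, with a median of -0.04 (camera adjusted p = 0.84). Among them miR-132-3p and miR-212-3p, induced together by neuronal activity, had log2 fold changes of -0.24 ± 0.17 and -0.43 ± 0.23. Of 10 astrocyte-enriched miRNAs, 6 were negative, with a median of -0.17 (camera adjusted p = 0.709), and miR-23b-3p had -0.45 ± 0.25. Of 8 oligodendrocyte-enriched miRNAs, 7 were negative, with a median of -0.05 (camera adjusted p = 0.696) that lay between miR-219a-2-3p and miR-219b, a pair with nearly equal counts. miR-219a-5p, which promotes oligodendrocyte maturation, had 110.3 ± 39.1 CPM in sham and 109.9 ± 27.7 CPM in injured animals, miR-338-3p, which shared its counts with miR-3065-5p, had a log2 fold change of -0.22 ± 0.27, and miR-23a-3p had -0.48 ± 0.28. In these 4 lists 0 members were called over all miRNAs and 0 when adjusted over the list alone. Neuron-enriched miRNAs took 34.6% ± 1.8 of reads in sham and 35.3% ± 0.6 in injured animals (exact permutation p = 0.6). Most of this share came from miR-9a-5p, at 203883 CPM in sham and 202669 CPM in injured animals, so it says little about the other members.

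**Figure D2:**
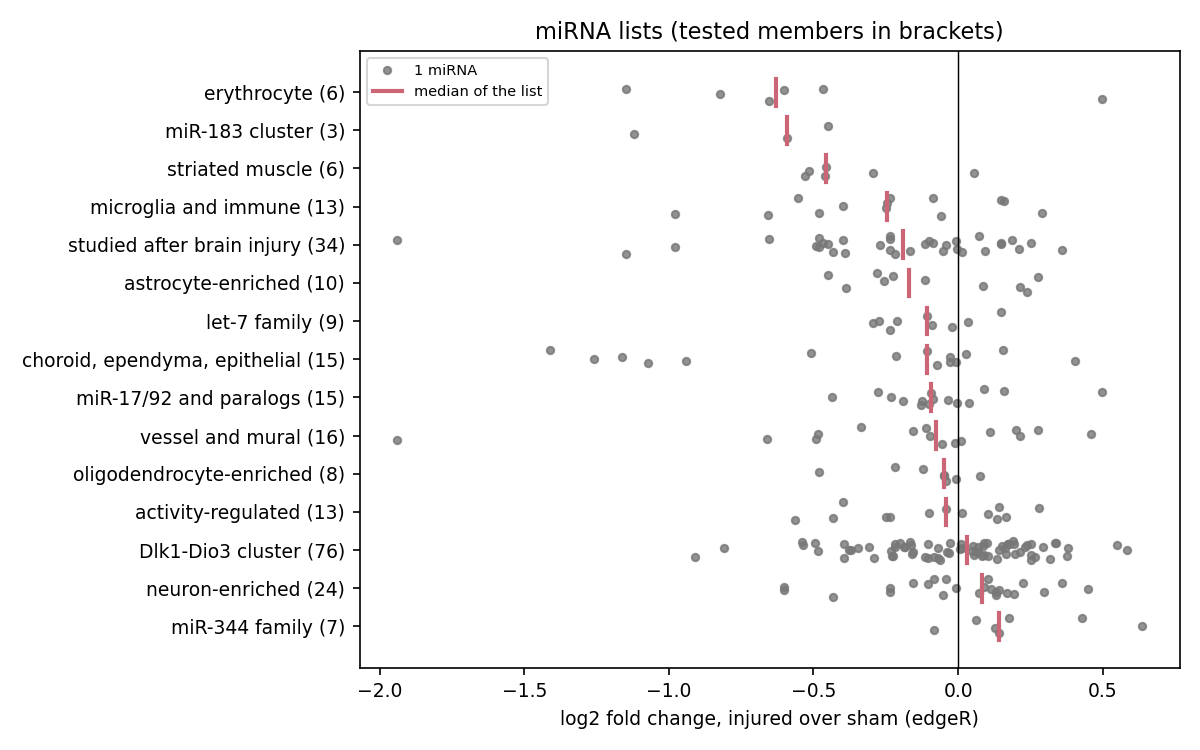
Log2 fold change of each tested member (grey points) of the 15 tested lists, injured over sham, with the median of each list as a red line and the number of tested members in brackets. The erythrocyte list had a median of -0.63 and was the only list that passed camera with its preset correlation (adjusted p = 0.0424), a call lost at an adjusted p = 0.558 with an estimated correlation.

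The vessel and mural list, which marks endothelial cells, pericytes and smooth muscle, had 10 negative and 6 positive members and a median of -0.08 (camera adjusted p = 0.391). miR-214-3p was its 1 call when adjusted over the list alone, at an adjusted p of 0.0244 from edgeR, against 0 calls over all miRNAs. That call was lost without any single library other than sham replicate 2, at adjusted p-values of 0.0744 without sham replicate 1, 0.101 without sham replicate 3, and 0.0841, 0.0607 and 0.125 without injured replicates 1, 2 and 3. Its 3 members at an unadjusted p under 0.05 were miR-214-3p, miR-195-5p and miR-199a-3p, the latter 2 at log2 fold changes of -0.66 and -0.49, and miR-152-3p had -0.48. Endothelial miR-126a-3p had a log2 fold change of -0.01 and smooth-muscle miR-145-5p -0.06. In the striated muscle list 5 of 6 members were negative, with a median of -0.46 (camera adjusted p = 0.0611), including miR-206-3p at -0.53 ± 0.24 and miR-1b at -0.52 ± 0.27 (SE). It passed at an adjusted p of 0.00665 without sham replicate 1, and the adjusted p with an estimated correlation was 0.59. In the muscle list 0 members were called over all miRNAs and 0 when adjusted over the list alone. The caudal Hox-cluster list had only 2 tested members, miR-10a-5p and miR-10b-5p, and took 0.00500% ± 0.00327 of reads in sham and 0.00677% ± 0.00304 in injured animals (SD, n = 3 each; exact permutation p = 0.5), with 0 calls over all miRNAs and 0 adjusted over the list alone.

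Epithelial miRNAs of the miR-200 family differed widely between libraries of either group. The miR-200 family (miR-200a-3p, miR-200b-3p, miR-200c-3p, miR-141-3p and miR-429) summed to 3528, 48.0 and 197.3 CPM in sham replicates 1, 2 and 3 and to 7.68, 1715 and 124.5 CPM in injured replicates 1, 2 and 3 (exact permutation p = 0.7). miR-204-5p, the leading miRNA of the choroid plexus, ranged only from 447.5 to 623.5 CPM. The choroid plexus, ependyma and epithelium list had 12 negative and 3 positive members and a median of -0.11 (camera adjusted p = 0.696), with miR-34c-3p at -0.51 ± 0.33 and miR-211-5p at 0.41 ± 0.30 (SE). The negative members include all those of the miR-200 family named above, from miR-200a-3p at -0.94 ± 1.91 to miR-141-3p at -1.41 ± 1.48. The count is therefore not separate from the spread of that family. In the miR-183 cluster, expressed in sensory cells, the 3 tested members had a median of -0.59 and a mean of -0.72 while camera's direction was up (adjusted p = 0.973). miR-182 had -1.12 ± 1.10 and miR-183-5p, which shared its counts with miR-3553, -0.59 ± 1.27. In both lists 0 members were called over all miRNAs and 0 when adjusted over the list alone.

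**Figure D3:**
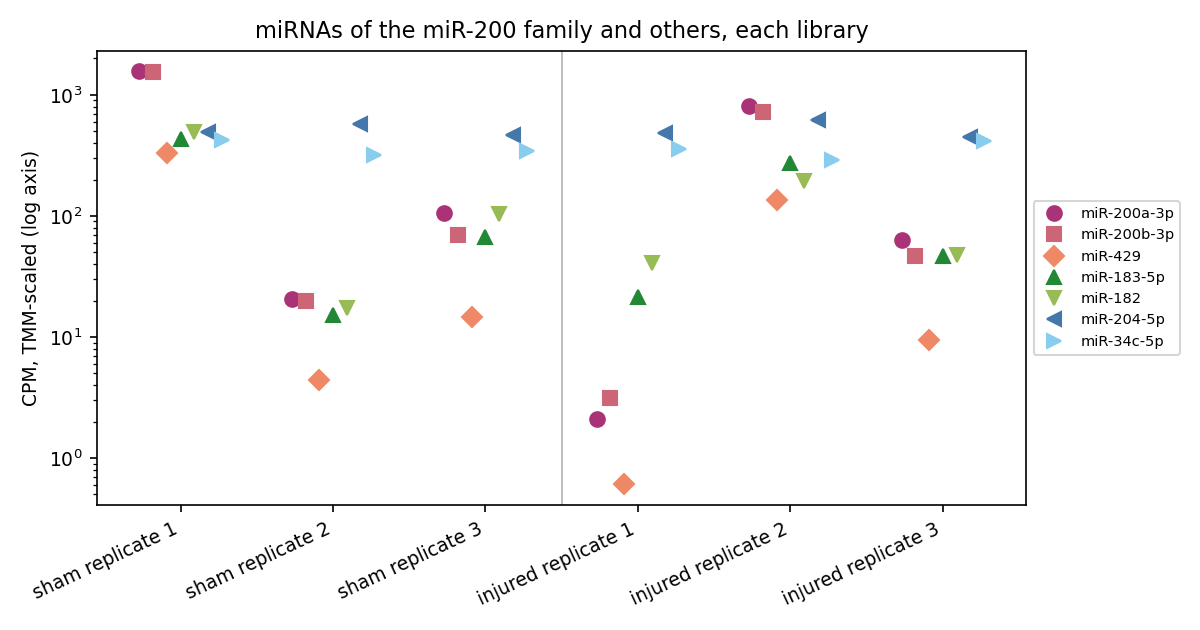
Level of 3 miRNAs of the miR-200 family, 2 of the miR-183 cluster and 2 of the choroid plexus and ependyma in each library, in TMM-scaled CPM on a log axis, with symbols side by side for legibility. miR-200a-3p was at 1564 CPM in sham replicate 1 and 2.09 CPM in injured replicate 1, while miR-204-5p was at 490.4 and 485.5 CPM there.

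Among genomic clusters and families, the imprinted Dlk1-Dio3 cluster had 41 positive and 35 negative members of 76. Its median was 0.03 and camera's direction was up, while the mean was -0.02 (camera adjusted p = 0.612). Its members with the smallest p were miR-337-3p and miR-382-3p, the latter at a log2 fold change of -0.81 ± 0.39 (SE) with counts close to those of miR-3592. The miR-17/92 cluster and its paralogs had 11 of 15 members negative and a median of -0.09 (camera adjusted p = 0.788), with miR-106b-5p at -0.44 ± 0.24. In the miR-344 family 6 of 7 members were positive, with a median of 0.14 (camera adjusted p = 0.0673). Its members miR-344i and miR-344b-5p had 0.64 ± 0.30 and 0.43 ± 0.37. The family passed at adjusted p-values of 0.0313 without sham replicate 2 and 0.0469 without injured replicate 3, and had 0.59 with an estimated correlation. Of 9 let-7 miRNAs, several of which shared nearly all counts with a miR-3596 name, 7 were negative, with a median of -0.11 (camera adjusted p = 0.478), including miR-98-5p at -0.29 ± 0.15 and let-7b-5p at -0.27 ± 0.19. In these 4 lists 0 members were called over all miRNAs and 0 when adjusted over the list alone. The let-7 family took 5.06% ± 0.10 of reads in sham and 4.70% ± 0.05 in injured animals (SD, n = 3 each). The groups did not overlap, and the exact permutation p of 0.1 was the smallest this design allows. Adjusted over the 16 shares it was 0.8, and no other list reached a p of 0.1. The median was negative for 12 of the 15 tested lists. With upper-quartile factors 6 of these turned positive, those of the activity-regulated, oligodendrocyte, vessel, choroid plexus, miR-17/92 and let-7 lists, and with library totals the positive median of the Dlk1-Dio3 list turned negative.

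The choice of the 5p or 3p arm, which is made when a hairpin's duplex is loaded into an Argonaute protein, did not differ detectably. Of 153 hairpins, 82 gave mainly the 5p and 71 mainly the 3p arm, and 142 had the same leading arm in all 6 libraries. These include 4 pairs of hairpins that shared counts of an arm, such as miR-130a and miR-3590, which enter with opposite arms. With 1 row per near-duplicate pair there were 148 hairpins, 80 with mainly the 5p and 68 with mainly the 3p arm. miR-26b had a log2 ratio of 5p to 3p of 9.21 ± 0.16 in sham and 8.16 ± 0.62 in injured animals (SD, n = 3 each). Its difference was -1.06 ± 0.33 (SE) with an adjusted p of 0.845 from limma. miR-337 had 6.63 ± 0.53 in sham and 7.54 ± 0.17 in injured animals, a difference of 0.91 ± 0.31. With limma 0 hairpins passed the test, 5 had an unadjusted p under 0.05 and chance gives 7.65, and no other tool was run on the ratios.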

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

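Of the alternatives, the fits without the 2 libraries highest in the miR-200 family, with 1 row per near-duplicate pair, with that family as a covariate and with the other form of the edgeR fit were chosen after the data were seen. The number of changed miRNAs was 0 in 24 of 25 alternatives, with 5 to 30 at an unadjusted p under 0.05. It was 1 without the 2 libraries highest in the miR-200 family, where miR-293-5p reached a log2 fold change of 4.53. For the named miRNAs, 909 alternative values gave none past the threshold, and the lowest adjusted p was 0.052 (DESeq2, miR-214-3p). Arm usage gave 0 calls in all 11 alternatives. Of 144 alternative values of the list shares, 142 moved by less than the spread between replicates. The log2 ratio of the let-7 share, -0.11, was -0.13 with 1 row per near-duplicate pair, its largest move, and -0.10 at its highest, and that of the choroid plexus list went from -0.60 to 0.48 without sham replicate 1.

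The number of lists called was 1 as reported, 0 with an estimated correlation and 0 with fry. It was 2 with library totals only, 2 with 1 row per near-duplicate pair, 2 without the 2 libraries highest in the miR-200 family, and 1 to 2 without each library in turn. The cause was not tested, but for the erythrocyte list the estimated correlation, -0.058, lay below the preset 0.01. The erythrocyte list, with a median of -0.63 that these tests cannot move, was not called with an estimated correlation or with fry. Its median ran from -0.71 to -0.51 without each library in turn and was -0.48 with upper-quartile factors. Upper-quartile factors moved the median of all miRNAs by 0.15 against TMM, giving 343 positive values in place of 244, so signs of values near 0 rest on the scaling. Under 8 alternatives the brain injury, striated muscle or miR-344 list passed, in its reported direction. No called result changed its sign. Of miRNAs simulated with a 2-fold change, 25.4% were recovered in a set where many others changed too. Recovery after adjustment is lower where few miRNAs differ, which further limits what a count of 0 can show.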

Other observations

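The tests of choroid plexus, the injury, olfactory tissue, residual blood and separate molecules were chosen after the patterns were seen, and those of vessel cells, single libraries, overlapping loci and other splits before their results were.

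Several miRNAs were present in some animals and nearly absent in others of the same group. miR-6321 had 496 reads in sham replicate 3 and 509 in injured replicate 3, 32 in injured replicate 1, and 0 in each of the other 3 libraries. Of the miR-290 cluster, known from embryonic stem cells, miR-292-5p and miR-291a-3p were highest in injured replicate 1, with 579 and 52 reads, and miR-293-5p was highest in injured replicate 3, with 88. In injured replicate 2 they had 1, 0 and 1 reads. miR-122-5p, the leading miRNA of liver, had 18 reads in injured replicate 1 and 131 to 485 in the other 5 libraries. Abundant miRNAs also differed within groups, and neuronal miR-7a-5p ranged from 4894 CPM in injured replicate 3 to 15191 CPM in injured replicate 2. These miRNAs were named for their spread after it was seen.

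The miR-200 family ranged 459.5-fold over the 6 libraries, where the median miRNA ranged 1.65-fold, and it led the first principal component, which held 47.9% of the variance and placed sham replicate 1 and injured replicate 2 at one end (-11.9 and -9.99) and injured replicate 1 at the other (12.2). The injury is excluded as the whole cause, since the range was 73.6-fold among the sham libraries alone. Choroid plexus tissue is argued against by miR-204-5p, which differed by 4.88 CPM between the libraries highest and lowest in miR-200a-3p, which differed by 1562 CPM. A hypothesis is that dissections may have held different amounts of olfactory tissue, where the family is abundant. The miR-183 cluster ranged 28.0-fold, with miR-182 from 17.4 to 489.5 CPM, but it was noticed together with the family, so this explanation stays open.

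The erythrocyte list was lower in injured animals under camera's preset correlation, with an adjusted p = 0.558 with an estimated correlation, and 3 of its 6 tested members also stand in the brain injury list and 1 in the miR-17/92 list. Fewer vessel cells are argued against for endothelium and smooth muscle by miR-126a-3p, miR-126a-5p, miR-143-3p and miR-145-5p. Their mean log2 fold change was 0.025, with an SE of 0.052 from log2 CPM. This does not cover cells marked by other members of the vessel list, such as miR-214-3p at -1.94 and miR-195-5p at -0.66. Of those averaged, miR-143-3p, at 0.28, also stands in the astrocyte list. miR-126a-3p, miR-126a-5p and miR-145-5p had -0.01, -0.11 and -0.06. Less residual blood in the injured tissue may account for the difference, but this stays open. The mean log2 fold change of miR-144-3p and miR-144-5p was -0.74, with an SE of 0.48 and an exact permutation p of 0.3 from log2 CPM. Both are members of the list, so their mean is part of the pattern and cannot decide its cause. That single libraries set the call also stays open, since the adjusted p rose to 0.151 without sham replicate 2 and to 0.124 without injured replicate 3, while the median of -0.63 stayed at -0.57 and -0.51 in these smaller fits. An effect of the injury on these miRNAs in brain cells was not tested.

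There were 30 pairs of names with counts within 5% of each other in every library, and their second names held 22.2% to 24.9% of reads. Separate counting of equally abundant molecules is excluded for the 10 pairs whose counts were identical in all 6 libraries, among them let-7a-5p with miR-3596a. This does not show that only a single molecule of a pair was present. miR-129-1-3p and miR-129-2-3p, also identical, come from loci that did not overlap. In all, 24 of the 30 pairs differed by less than counting noise gives, which the 5% limit partly sets for pairs with few reads. Loci overlapped for 29 of the 30 pairs, against 3 of 996 random pairs, in line with reads being counted under both names.

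Among the 10 splits of the 6 libraries into groups of 3, which are too few for a share under 0.05, the real split gave 0 changed miRNAs and the highest other gave 1. With 0 in the real split no other could give fewer, so this comparison cannot decide. For lists, 7 of the 10 splits gave at least the 1 call of the real split, and the highest other gave 3. The unadjusted camera p of the erythrocyte list was 0.00283 in the real split and 0.0456 to 0.674 in the other 9. This list was singled out because it was called in the real split, so its smaller p there follows in part from that choice. The comparison therefore gives no support to the call. For arm usage all 10 gave 0, and the same limit holds. At an unadjusted p under 0.05 the real split had 12 miRNAs and the others 3 to 77.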
